A study of Mus musculus with 6 samples.

How the data were processed

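The data are bulk RNA sequencing of epithelial cells from mouse lungs at embryonic day 16.5. Per the labels' protocols, lungs were digested to single cells, EpCAM-positive cells were taken by flow sorting, RNA was prepared from frozen pellets, stranded libraries of polyadenylated RNA were made and all were sequenced on an Illumina HiSeq instrument. Per the labels, the 6 libraries ran in 1 lane, so no sequencing batch separates the genotypes. The authors deposited 1 table of raw counts per gene. Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, counted with featureCounts and handled with edgeR 3.16.5 and limma 3.30.12, on the mm10 build. The aligner, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Gapdh, which has many processed copies in the genome, held 4.44 to 7.06 CPM (counts scaled to the same library size), so genes with near-identical copies can be undercounted in this table.

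The deposited counts are whole numbers for 27179 Entrez gene identifiers, of which 6567 were at 0 in each library. No row lacked a gene and no column was left unused. Gene symbols and mm10 coordinates came from a RefSeq gene table, which matched 25275 identifiers (92.99%) and 99.19% of the counts. Totals were 13472216, 16386541 and 15435418 in control replicates 1, 3 and 7 and 16517427, 15440843 and 17228762 in Grhl2_cKO replicates 1, 5 and 10. A count of 3, the limit that a count of 0 allows, is 0.174 to 0.223 CPM. Such limits cover counting error only. Replicates of a group differed by more than counting noise in each pair (chi-square per degree of freedom 7.72 to 12.9 over genes with 20 or more counts), so none was a library deposited again.

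Groups were taken from the genotype in the sample descriptions, and all 6 samples were used. The main test was edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM factors (0.981 to 1.009), filterByExpr by group (minimum count 10, minimum total 15; 14842 genes tested, 12337 left out), estimateDisp, glmQLFit and glmQLFTest with default settings and no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. Fold changes use a prior count of 0.125. The standard error is the size of the log2 fold change over the square root of F. The common biological coefficient of variation was 9.5%. CPM values are computed here on TMM-scaled library sizes. The 29 gene lists, 596 genes with the sex check included, of which 2 were not matched, were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists, with an estimated correlation beside it, and with fry.

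Tests, lists and named genes were fixed before the data were examined. The named genes are Grhl2; the 12 largest rises and 12 largest falls among called genes with a mean count of 50 or more, no overlap of CPM between groups and a symbol that is not a placeholder; up to 4 members of each list with the smallest p; and 19 fixed markers. Alternatives were RLE, upper-quartile and total-count scaling, no filter (1 count or more in total), a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust and legacy quasi-likelihood, sex as a covariate, and leaving out each library in turn. The lists were rerun under the changes of scaling, filter, covariate and samples.

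The test was run on simulated counts with the means and library sizes of the real samples and known changes in some genes. For the comparison of Grhl2_cKO with control, over 14710 genes, edgeR recovered 70.8% of 65 genes changed 1.5-fold, 86.4% of 66 changed 2-fold and 100% of 65 changed 4-fold, with 15 false calls among 183. With no changed genes it made 2 calls. Camera called only the list that was lowered. Simulated genes varied independently of each other, so this run does not test camera on lists whose members vary together. The series design mentions cell populations in the plural, and only EpCAM-positive samples were analysed here. Some genes that the naming rule covers are not reported here.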

Results

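Messenger RNA was measured in epithelial cells sorted from the lungs of mouse embryos at E16.5 (embryonic day). Shh-Cre, a Cre recombinase driven by the Sonic hedgehog gene, acts in the embryonic lung epithelium, and the floxed gene was Grhl2, which encodes the epithelial transcription factor grainyhead-like 2. Control samples carried 1 floxed and 1 intact Grhl2 allele (n = 3, replicates 1, 3 and 7), and knockout samples, called Grhl2_cKO, carried 1 floxed allele and 1 null allele (n = 3, replicates 1, 5 and 10). Both genotypes carried Shh-Cre, so control cells in which Cre acted keep 1 Grhl2 allele, and values given as a share of control are relative to that state and not to an undeleted level. Each genotype had 2 male samples and 1 female sample. Cells positive for EpCAM, an epithelial surface protein, were taken by flow sorting. Total gene counts were 13472216 to 17228762 per library, and Sftpc was the most abundant gene in each library, with 1.27% to 1.56% of the counts. Xist stood at 2386 CPM or more in the libraries labelled female and at 3.43 CPM or less in those labelled male, so the sex labels and the counts matched in 6 of 6 libraries. It is not stated whether each sample came from 1 embryo, so the p-values measure the spread between these samples.

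Grhl2 (Entrez 252973, chromosome 15, 37232821 to 37363569, mm10) was lower in the knockout libraries. It stood at 149.2, 147.9 and 145.98 CPM in control replicates 1, 3 and 7, and at 105.3, 109.2 and 115.3 CPM in Grhl2_cKO replicates 1, 5 and 10. The log2 fold change was -0.43 ± 0.06 (SE, n = 3 per group; edgeR adjusted p = 0.0026), which left 74.4% of the control level. The labels do not name the floxed exons, and the counts are sums over the gene, so reads from exons outside the deleted part can remain. Of the related factors, Grhl3 had a log2 fold change of 0.45 ± 0.12 (edgeR adjusted p = 0.0899), Ovol1 stood at 50.2% of control (edgeR adjusted p = 0.0959; called with DESeq2, adjusted p = 0.0406, in a range of 0.0406 to 0.276) and Ovol2 had a log2 fold change of -0.58 ± 0.17 (edgeR adjusted p = 0.121), none past the threshold in the edgeR test. The list of grainyhead and OVOL factors lay lower than other genes by camera (adjusted p = 0.0416; adjusted p = 0.358 with an estimated correlation), with Grhl2 itself the 1 called member of 8, and the call was lost with sex as a covariate (adjusted p = 0.0545) and in 5 of the 6 fits without 1 library (0.0559 to 0.0866), within a range of 0.0244 to 0.358 over its alternatives. Adjusted over the list alone, 3 members fell and 1 rose.

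The comparison of the genotypes asked which genes of the lung epithelium differ when Grhl2 is deleted. Of 14842 genes tested, 537 changed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 355 lower and 182 higher in Grhl2_cKO. Lower genes made up 66.1% of the calls. The median fold was 1.72 among lower genes and 1.5 among higher genes. At least 2-fold changes were found for 139 lower and 35 higher genes. The CPM of the groups did not overlap for 2680 genes, 18.1% of those tested, where chance gives 10% with 3 against 3. The count of called genes was 249 without Grhl2_cKO replicate 10, 257 without Grhl2_cKO replicate 5, 302 without control replicate 3 and 335 without control replicate 7, and the count of at least 2-fold changes was 93 and 107 without Grhl2_cKO replicates 10 and 5. Higher genes numbered 79, 91, 78 and 92 in these 4 fits, against 182, and lower genes 170, 166, 224 and 243, against 355. At least 2-fold higher genes numbered 20, 21, 17 and 21, against 35, and at least 2-fold lower genes 73, 86, 106 and 123, against 139.

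**Figure D1:**
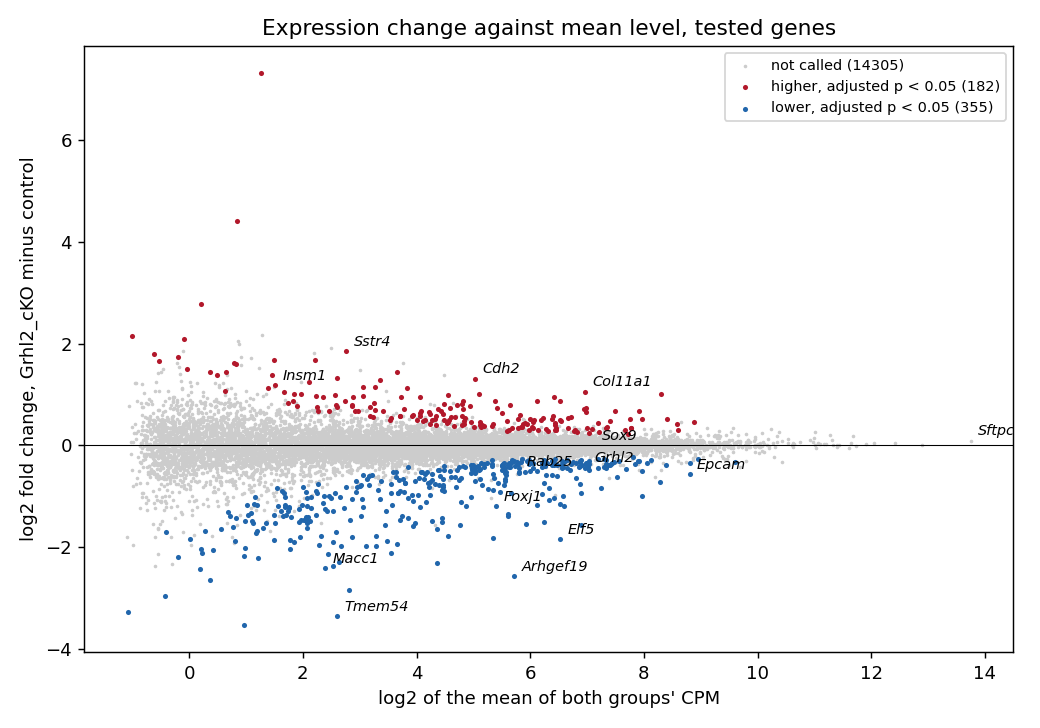
Log2 fold change (Grhl2_cKO minus control) of each tested gene against the log2 of its mean CPM over both groups; blue points are the 355 genes called lower, red points the 182 called higher, and grey points the genes not called. Changes of at least 2-fold were called for 139 lower and 35 higher genes.

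Among called genes with a mean of 50 or more counts and a symbol that is not a placeholder, the 12 largest falls left 9.77% to 25.4% of control. Tmem54, a membrane protein gene (Entrez 66260, chromosome 4, 129105529 to 129111626), fell from 11.1 ± 1.17 to 1.07 ± 0.43 CPM (SD, n = 3 each; log2 fold change -3.36 ± 0.23 SE, edgeR adjusted p = 5.69e-05). Rbbp8nl fell to 13.8% of control, and Arhgef19, which encodes a guanine nucleotide exchange factor (Entrez 213649, chromosome 4, 141239605 to 141257915), fell from 90.1 ± 7.85 to 15.2 ± 2.45 CPM (log2 fold change -2.57 ± 0.12 SE, edgeR adjusted p = 3.59e-06). Macc1 fell to 18.7% of control, Cers3, a ceramide synthase gene, to 19.2%, Il17re, an interleukin 17 receptor subunit gene, to 20.1%, and Mlph, which encodes the vesicle transport protein melanophilin, to 20.3%. Ceacam1, a cell adhesion gene, fell to 22.7%, Nectin4, an adherens junction gene, to 23.2%, Lyz1, a lysozyme gene, to 24.4%, Cfap65, a gene of motile cilia, to 25.3% and Bnipl to 25.4% of control. EdgeR adjusted p-values of these 12 genes were 0.0187 or less. Lyz1 shares much of its sequence with Lyz2, so its counts are uncertain. It stood at 2.53 CPM in Grhl2_cKO replicate 1 against 1.03 and 0.47 CPM in replicates 5 and 10, and its log2 fold change of -2.03 was -2.88 without replicate 1. Its call was lost without control replicate 3 (adjusted p = 0.0676) and without Grhl2_cKO replicate 5 (0.0773), the highest of its alternatives, the lowest being 9.49e-06.

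Among the 12 largest rises by the same rule, Cdh2, which encodes N-cadherin (Entrez 12558, chromosome 18, 16588877 to 16809246), went from 18.7 ± 1.1 to 46.5 ± 2.21 CPM (SD, n = 3 each; log2 fold change 1.31 ± 0.08 SE, edgeR adjusted p = 2.62e-05). Sstr4, a somatostatin receptor gene, rose 3.62-fold, Slc6a4, the serotonin transporter gene, 3.20-fold, the long noncoding RNA Miat 2.74-fold and Dio3os 2.50-fold. Dio3os lies antisense to Dio3, and the strand setting of the counting is not given in the sources used here, so its counts are uncertain. Olfml1 rose 2.42-fold, Dpysl4 2.39-fold, Pcdh7, a protocadherin gene, 2.22-fold, Ky 2.21-fold, the receptor tyrosine kinase gene Ret from 9.03 to 19.6 CPM, the collagen gene Col11a1 2.08-fold, from 81.4 ± 5.76 to 169.3 ± 12.9 CPM, and Kcnip2 2.07-fold. EdgeR adjusted p-values of these 12 genes were 0.0155 or less. Dpysl4 lost its call without control replicate 3 (adjusted p = 0.0683) and Grhl2_cKO replicate 10 (0.0603), with 0.000428 to 0.0683 over its alternatives. Kcnip2 lost it without control replicates 3 (0.0717) and 7 (0.0517) and Grhl2_cKO replicate 10 (0.0669), with 0.0111 to 0.0717 over its alternatives.

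The list of epithelial splicing, vesicle trafficking and surface protease genes lay lower. Of 26 measured members 11 fell (15 adjusted over the list alone), none rose and 25 had a log2 fold change below 0, with a median of -0.22 (camera adjusted p = 2.99e-33). This was the 1 list of 29 that was also called with an estimated correlation (adjusted p = 0.0245). Besides Arhgef19 and Macc1, the transcription factor gene Elf5 fell from 144.1 ± 1.25 to 40.1 ± 9.86 CPM (SD, n = 3 each; log2 fold change -1.84 ± 0.14 SE, edgeR adjusted p = 8.46e-05) and the receptor gene Erbb3 to 56.2% of control (edgeR adjusted p = 0.00015). The splicing factor genes Esrp1 and Esrp2 did not pass, with log2 fold changes of -0.06 ± 0.05 and -0.17 ± 0.07 (edgeR adjusted p = 0.785 and 0.329). Rab25, a vesicle trafficking gene, fell to 70.0% of control (edgeR adjusted p = 0.0394), a call that was lost with sex as a covariate and in 5 of the 6 fits without 1 library, all but that without control replicate 7 (adjusted p from 0.00115 to 0.129 over its alternatives).

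Junction genes fell in part. In the tight junction and apical polarity list 5 of 26 members fell (5 adjusted over the list alone) and none rose (camera adjusted p = 0.000122; adjusted p = 0.516 with an estimated correlation). Cgn, which encodes cingulin, fell to 58.7% of control, Cldn4 to 44.3%, Ildr1 to 61.5% and Tjp3 to 70.7% (edgeR adjusted p from 0.00044 to 0.0103). Cldn4 was spread widely among controls, at 96.9 ± 30.3 CPM (SD), and was not called with robust quasi-likelihood (adjusted p = 0.101, the highest of its alternatives, the lowest being 0.00219), and Tjp3 was not called without Grhl2_cKO replicate 5 (0.0512; 6.23e-05 to 0.0512). In the adherens junction and desmosome list 6 of 20 members fell and 2 rose (10 and 2 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 4.35e-07; adjusted p = 0.414 with an estimated correlation). The plakin genes Ppl and Dsp fell to 56.1% and 70.6% of control. Epcam, the gene of the protein used for the sort (Entrez 17075, chromosome 17, 87635979 to 87651127), fell from 534.6 ± 29.7 to 361.3 ± 36.2 CPM (log2 fold change -0.56 ± 0.08 SE, edgeR adjusted p = 0.00412). Whether the sort took the same cells from both genotypes was not tested, and this limit holds for the cell-type lists below. Cdh1, which encodes E-cadherin, stood at 769.8 ± 90.0 and 639.0 ± 55.0 CPM, a log2 fold change of -0.27 ± 0.10 that did not pass (edgeR adjusted p = 0.21). Of 6 epithelial keratins, 2 fell, or 5 adjusted over the list alone (camera adjusted p = 3.45e-06; adjusted p = 0.35 with an estimated correlation): Krt23 to 38.2% and Krt80 to 49.6% of control, the latter called in 4 of 16 alternatives (edgeR adjusted p = 0.0499; 0.0284 to 0.169 over its alternatives). Krt8 and Krt18 had log2 fold changes of -0.48 ± 0.13 and -0.37 ± 0.15 (edgeR adjusted p = 0.0832 and 0.317), though Krt8 was called with DESeq2 (adjusted p = 0.0022; 0.0022 to 0.258 over its alternatives).

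**Figure D2:**
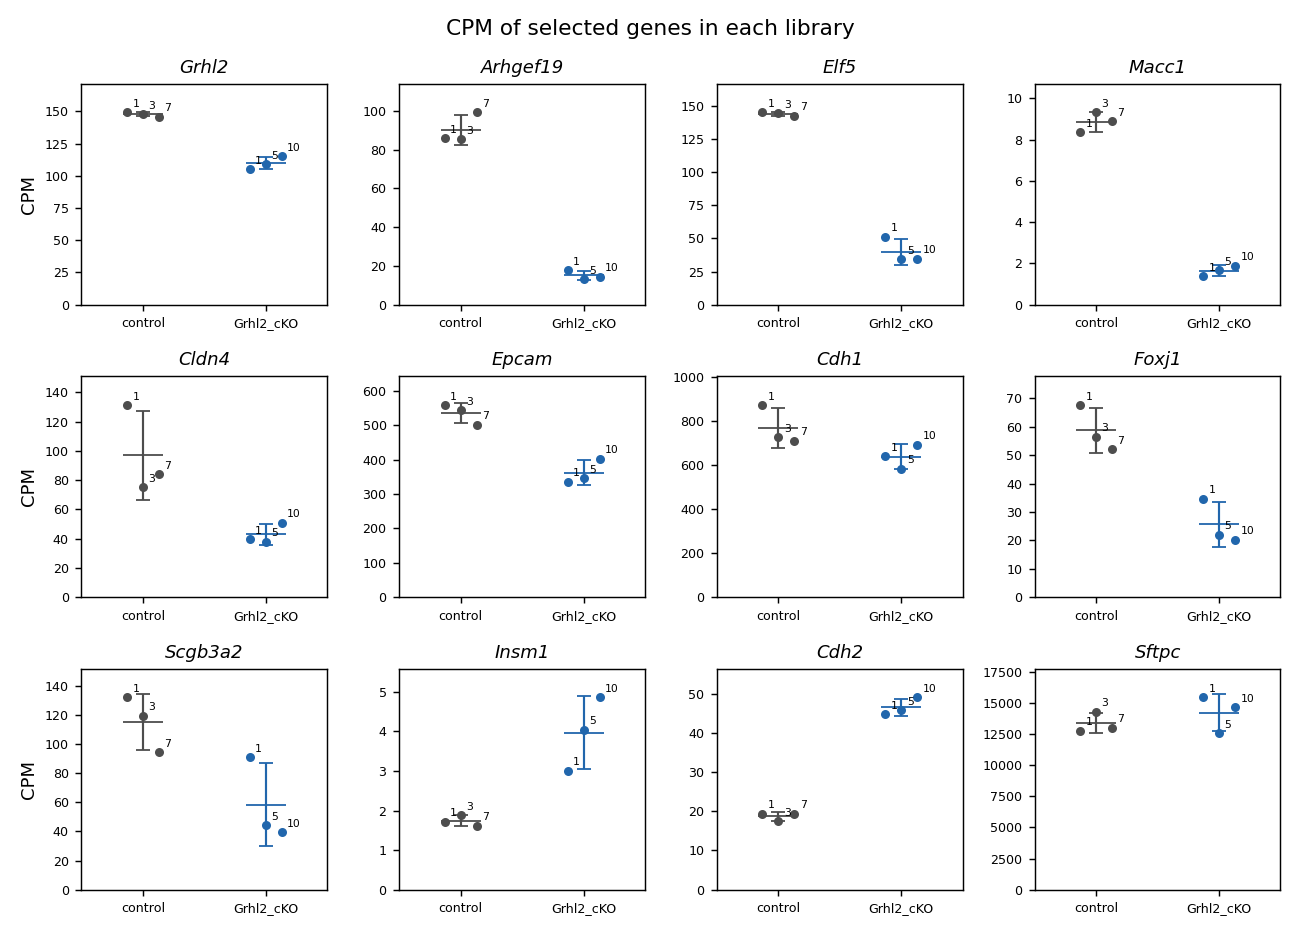
CPM of 12 genes in each library, with the replicate number beside each point and the group mean ± SD as a bar (n = 3 per group; each panel has its own axis from 0). Grhl2, Arhgef19, Elf5 and Foxj1 lay lower in each Grhl2_cKO library than in every control library, Cdh2 and Insm1 higher, and the groups overlapped for Sftpc.

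Markers of ciliated and secretory airway cells were lower in Grhl2_cKO. In the ciliated list 15 of 30 members fell (21 adjusted over the list alone) and none rose, with a median of 48.3% of control (camera adjusted p = 5.74e-26; adjusted p = 0.35 with an estimated correlation). Foxj1, the transcription factor gene of motile cilia (chromosome 11, 116330704 to 116335499), fell from 58.8 ± 8.03 to 25.7 ± 7.86 CPM (SD, n = 3 each; log2 fold change -1.19 ± 0.18 SE, edgeR adjusted p = 0.00597). The dynein genes Dnah5 and Dnah11 fell to 35.9% and 51.0% of control and Myb, which acts early in ciliated cells, to 63.7%. Dnah5 lies within 10 Mb of Grhl2, and an effect of sequence flanking the null allele on it was not separated. Grhl2_cKO replicate 1 held 34.7 CPM of Foxj1 against 22.03 and 20.3 CPM in replicates 5 and 10. Its summed heart muscle markers also stood apart, at 436.4 CPM against 172.0 to 232.2 CPM in the other 5 libraries. In the secretory list 5 of 15 members fell (10 adjusted over the list alone) and all 15 lay below 0, with a median of 52.7% of control (camera adjusted p = 1.86e-18; adjusted p = 0.35 with an estimated correlation). Aldh1a7 fell from 332.3 to 166.0 CPM, Aldh1a1 to 52.7% of control, Lypd2 to 29.1% and Cbr2 to 33.6% (edgeR adjusted p from 0.00033 to 0.0151). Aldh1a1 and Aldh1a7 are close paralogs, so their counts are uncertain. Cbr2 lost its call with robust quasi-likelihood (adjusted p = 0.172) and without Grhl2_cKO replicate 10 (0.0715), with 0.00294 to 0.172 over its alternatives. Scgb3a2 stood at 115.2 ± 19.2 and 58.3 ± 28.3 CPM and did not pass (edgeR adjusted p = 0.0857). Grhl2_cKO replicate 1 held 90.9 CPM of it against 44.4 and 39.6 CPM in replicates 5 and 10, and without replicate 1 it was called (edgeR adjusted p = 0.000589), as with limma-voom (0.0466), in a range of 0.000589 to 0.423 over its alternatives. Scgb1a1 was low, at 2.68 ± 0.75 and 2.06 ± 1.77 CPM (edgeR adjusted p = 0.896). Grhl2_cKO replicate 1 held 4.09 CPM of it against 0.83 and 1.24 CPM in replicates 5 and 10, and without replicate 1 the log2 fold change was -1.34 in place of -0.36, not called (adjusted p = 0.084; 0.084 to 1 over its alternatives).

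The list of neuroendocrine markers, named for a rare airway epithelial cell type, lay higher. Of 17 members 4 rose (8 adjusted over the list alone), none fell, and the median was 131.5% of control (camera adjusted p = 4e-07; adjusted p = 0.414 with an estimated correlation). Insm1, a transcription factor gene of these cells, rose from 1.74 ± 0.14 to 3.97 ± 0.93 CPM (SD, n = 3 each; log2 fold change 1.18 ± 0.23 SE, edgeR adjusted p = 0.021). Celf3 rose 1.93-fold and Cplx2 1.26-fold (edgeR adjusted p = 0.0147 and 0.0384). Insm1 and Celf3 were at low levels, and each lost the call in the same 4 fits, without control replicate 3, control replicate 7, Grhl2_cKO replicate 5 or Grhl2_cKO replicate 10 (adjusted p over all alternatives 0.00812 to 0.0863 and 0.00306 to 0.0716), and Cplx2 in 5 fits (0.0118 to 0.13). Celf3 and Cplx2 are also expressed in neurons, and neuronal markers were measured beside this list. Tubb3 of the nerve list rose 6.92-fold (edgeR adjusted p = 0.0406; called in 8 of 15 alternatives, 0.000735 to 0.145) and was above every control in each Grhl2_cKO library, and all 6 tested members of that list lay above 0 (camera adjusted p = 0.0551). The sum of 8 airway neuron markers, chosen after values were seen, was 5.53 CPM in Grhl2_cKO replicate 1 and 2.50 and 2.49 CPM in replicates 5 and 10, against 2.01 to 2.99 CPM in controls. Counts from sorted bulk cells do not assign these transcripts to either cell type. Sox2, an airway progenitor factor, had a log2 fold change of -0.06 ± 0.13 (edgeR adjusted p = 0.957). The basal cell list had no call among 8 members (camera adjusted p = 0.974), and its factor Trp63 was low, at 0.50 and 0.73 CPM.

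Among alveolar and progenitor markers, type 2 genes moved in both directions. In the type 2 list 6 of 23 members fell and 1 rose (10 and 3 adjusted over the list alone), with a median of 84.7% of control (camera adjusted p = 0.00496; adjusted p = 0.653 with an estimated correlation; adjusted p = 0.1 without Grhl2_cKO replicate 5, in a range of 4.29e-07 to 0.653). Il33 fell to 35.8% of control and Cebpa to 73.6%, while the complement gene Hc rose 1.82-fold (edgeR adjusted p = 0.00611, 0.0199 and 0.00453). Cebpa was not called without control replicate 7 or Grhl2_cKO replicates 5 and 10 (0.0651, 0.0742 and 0.0863; 0.000296 to 0.0863 over its alternatives). Sftpc stood at 13374 ± 818 CPM in controls and 14229 ± 1472 CPM in Grhl2_cKO (edgeR adjusted p = 0.945). The type 1 list was not called (camera adjusted p = 0.114), with 2 of 23 members higher (4 higher and 1 lower adjusted over the list alone), Col4a3 1.41-fold and Igfbp2 1.37-fold (edgeR adjusted p = 0.00715 and 0.0217). Without control replicate 1 or Grhl2_cKO replicate 5 this list was called higher (camera adjusted p = 1.21e-05 and 0.0258; 1.21e-05 to 0.968 over its alternatives), and Igfbp2 was not called without control replicate 3 or Grhl2_cKO replicate 5 (0.0848 and 0.0651; 1.19e-05 to 0.0848). Ager and Hopx did not pass (edgeR adjusted p = 0.731 and 0.784). None of the 19 distal tip members was called in the main edgeR test (camera adjusted p = 0.121), including Sox9, at 140.6 ± 13.8 and 141.2 ± 14.8 CPM (edgeR adjusted p = 0.995), and Nkx2-1, at 680.3 ± 95 and 700.9 ± 94.6 CPM (edgeR adjusted p = 0.969). Bmp4 of this list was called higher with DESeq2 (adjusted p = 0.0149, in a range of 0.0149 to 0.254 over its alternatives). Without control replicate 7 or Grhl2_cKO replicate 1 the tip list was called higher (camera adjusted p = 0.0125 and 0.0168; 0.0125 to 0.777 over its alternatives).

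The list of mesenchymal transition factors lay higher (camera adjusted p = 6.95e-05; adjusted p = 0.414 with an estimated correlation), with Cdh2 and Tgfbi called higher of 18 members (3 adjusted over the list alone) and none lower. Tgfbi, which encodes an extracellular matrix protein, rose 1.60-fold (edgeR adjusted p = 0.00216). Vim and Zeb1 had log2 fold changes of 0.32 ± 0.09 and 0.29 ± 0.16 (edgeR adjusted p = 0.0895 and 0.53), and Vim was called with DESeq2 and without control replicate 1 (0.00889 and 0.0361; 0.00889 to 0.261 over its alternatives).

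**Figure D3:**
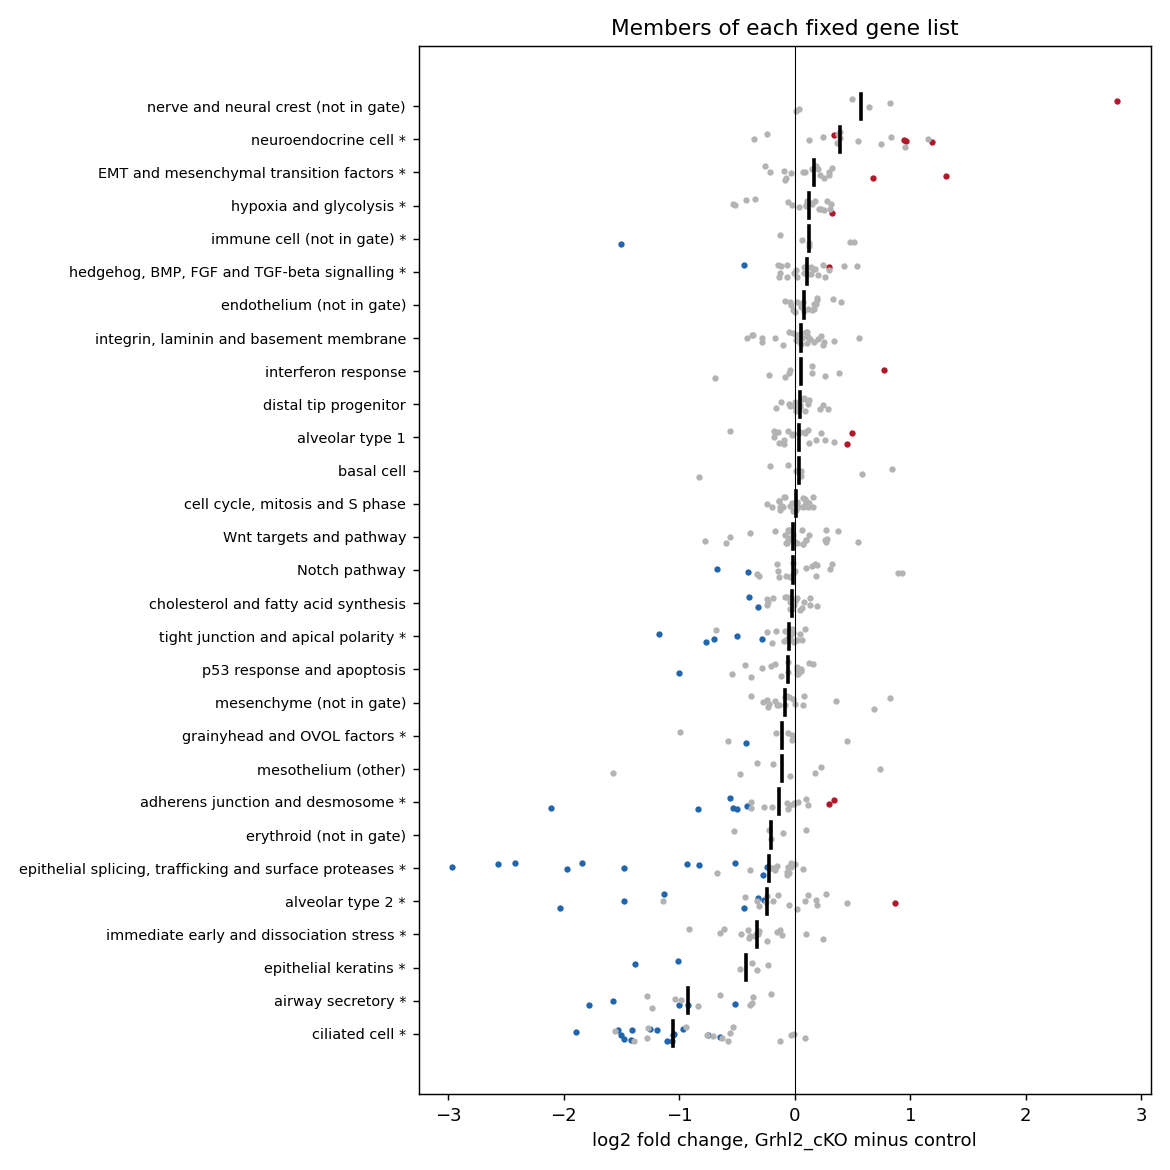
Log2 fold change (Grhl2_cKO minus control) of each tested member of the 29 lists, ordered by the list median (black bar); blue and red points passed the test for single genes, grey points did not, and an asterisk marks the 14 lists called by camera with the preset correlation. Ciliated and secretory airway lists have the lowest medians.

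Signalling and metabolic lists held few called genes. The hedgehog, BMP, FGF and TGF-beta list was called higher (camera adjusted p = 0.0416; adjusted p = 0.35 with an estimated correlation), with a median of 107.5% of control, Fgfr1 1.23-fold higher and Fgfr3 at 73.9% of control (edgeR adjusted p = 0.0449 and 0.0198). Fgfr1 was called in 9 of 16 alternatives (0.0116 to 0.146) and Fgfr3 in 13 (0.000149 to 0.0863). The hypoxia and glycolysis list was called higher (camera adjusted p = 0.0416; adjusted p = 0.653 with an estimated correlation), with 1 called member of 20, P4ha1, a collagen hydroxylase gene, 1.25-fold higher. Both list calls were lost without control replicate 3, control replicate 7 or Grhl2_cKO replicate 10 (camera adjusted p from 0.0906 to 0.245), and the hypoxia call also without Grhl2_cKO replicate 1 (0.0636). Over all alternatives the signalling list ranged from 0.00698 to 0.35 and the hypoxia list from 0.00061 to 0.653. Each of these lists had 2 members higher and 1 lower when adjusted over the list alone. The Notch list was not called (camera adjusted p = 0.439; its median is below 0 and its mean above), though Dtx4 and Nrarp fell to 75.3% and 62.8% of control (edgeR adjusted p = 0.00301 and 0.0155; Nrarp called in 13 of 16 alternatives, 0.00862 to 0.0664). In the cholesterol and fatty acid list (camera adjusted p = 0.217) Acly fell to 76.1% of control and Fasn by 0.32 on the log2 scale (edgeR adjusted p = 0.00266 and 0.02; Fasn called in 12 of 16 alternatives, 2e-05 to 0.11). The p53 list (camera adjusted p = 0.286) had 1 called member, Ddit4l, at 49.8% of control (called in 13 of 16 alternatives, 0.00436 to 0.0716), and the interferon list (camera adjusted p = 0.569) had Usp18, 1.71-fold higher (called in 8 of 16, 0.0319 to 0.179). In the main edgeR test no member was called in the lists of the cell cycle (32 members, camera adjusted p = 0.715; its median and test are above 0 and its mean below), Wnt pathway (28 members, adjusted p = 0.675; its median and mean are below 0 and its test above) and integrins and basement membrane (30 members, adjusted p = 0.328). With DESeq2, Ccnd1 of the Wnt list was called higher (adjusted p = 0.006, called in 4 of 16 alternatives). In the basement membrane list DESeq2 called Fras1 and Itga9 lower (adjusted p = 0.00496 and 0.0173) and Lama1 and Col4a6 higher (0.00396 and 0.0181). These were called in 5, 1, 2 and 3 of 16 alternatives. Adjusted over the list alone, 3 integrin and basement membrane genes rose and 2 fell, and 1 Notch gene rose and 4 fell. Adjusted the same way, the counts of the cholesterol, p53, interferon, cell cycle and Wnt lists did not differ from those over all genes. By fry in either direction, which needs no shared sign, the cholesterol (adjusted p = 6.01e-06) and Notch (0.000585) lists were called. So were the basement membrane (0.00493), Wnt (0.00666) and p53 (0.0438) lists, but not the cell cycle (0.39) or interferon (0.0589) lists.

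Markers of cells outside the gate were also counted. The mesenchyme (camera adjusted p = 0.439), endothelium (0.0922), erythroid (0.619), mesothelium (0.328) and nerve lists (0.0551) were not called. Without Grhl2_cKO replicate 1 the mesenchyme and mesothelium lists were called lower (camera adjusted p = 0.0223 and 0.000351, the latter in a range of 0.000351 to 0.954), and the mesenchyme list likewise without control replicate 7 (0.00272; 0.00272 to 0.832 over its alternatives). The endothelium list was called higher without control replicates 1 (0.0122) and 3 (0.0246) or Grhl2_cKO replicate 10 (0.0496), with 0.0122 to 0.979 over its alternatives. The nerve list was called higher with sex as a covariate (0.0421) and without Grhl2_cKO replicates 5 (0.0115) and 10 (0.0234), with 0.0115 to 0.543 over its alternatives. In the nerve list Tubb3, a neuronal tubulin gene, rose from 0.29 to 2.03 CPM (edgeR adjusted p = 0.0406; called in 8 of 15 alternatives, 0.000735 to 0.145). Grhl2_cKO replicate 1 held 3.67 CPM of it against 1.54 and 0.89 CPM in replicates 5 and 10, and without replicate 1 its log2 fold change was 2.04 in place of 2.79 and not called (adjusted p = 0.0578). The call was also lost without control replicates 1 (0.0559), 3 (0.145) and 7 (0.134) and Grhl2_cKO replicate 5 (0.0717). The immune list was called lower (camera adjusted p = 0.00241; adjusted p = 0.414 with an estimated correlation; 0.613 with no filter, 0.0634 without control replicate 3, 0.0978 and 0.276 without Grhl2_cKO replicates 5 and 10; 0.000777 to 0.613 over its alternatives), against a mean below 0 and a median above 0, and rested on Lcp1, which fell from 111.6 ± 2.66 to 39.3 ± 2.67 CPM (edgeR adjusted p = 3.59e-06). Other members stood far lower, such as Cd68 at 4.29 and 3.91 CPM. The list of immediate early and dissociation genes lay lower with no called member of 18 (camera adjusted p = 0.00291; adjusted p = 0.653 with an estimated correlation), and was not called without control replicate 1 (0.563; 2.14e-07 to 0.653 over its alternatives). Adjusted over the list alone, 3 of its members fell, as did 1 mesothelium gene.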

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

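The removal of genes near Grhl2 and the fit of male libraries were chosen after seeing the data. The 10 other settings that kept all 6 libraries called 452 genes (sex as a covariate) to 669 genes (DESeq2), against 537, and 83.1% or more of the 537 calls were kept in each, with no change of sign. Fits without 1 library called 249 to 504 genes, kept 45.3% to 77.1% of the 537 calls and changed the sign of none. For changes of at least 2-fold the range without 1 library was 93 to 203 genes, against 174. Fewer samples per fit lower the power, and further causes were not tested. Without the genes within 10 Mb of Grhl2, 532 genes were called, and with the 4 male libraries alone 386.

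Grhl2 was called lower in 16 of 16 alternatives, with log2 fold changes of -0.46 to -0.40. Of the 65 named genes other than Grhl2 that were called, 58 were called in each alternative with all 6 libraries and 44 in each fit. No called value of a named gene changed sign, and 16 of 1242 uncalled values did. Of the 14 lists called by camera, 10 to 12 stayed called without 1 library, where 12 to 15 lists were called with the newly called ones included. With an estimated correlation 1 list was called, and 1 by the directional fry test, which asks another question; fry in either direction called 18. Estimated correlations within the 14 lists reached 0.641, in the secretory list, and a high correlation widens the null of the test. The grainyhead (-0.063) and hedgehog, BMP, FGF and TGF-beta (-0.005) lists lost their calls without such a correlation. What else separates these counts was not tested. No paired analysis was possible because the labels used here do not give litters or pairs of samples. At this depth genes under about 1 CPM, such as Trp63, give wide intervals.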

Other observations

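The genes and tests in this part were chosen after their values or closely related values were seen. Outside the fixed lists, most genes with cilium-type symbols lay lower. The set held 60 tested genes not in the ciliated list, picked by symbol (such as Dnah, Cfap, Rsph, Tekt, Spag and some Ccdc genes). Of these, 18 fell, 1 rose and 51 lay below 0, with a median log2 fold change of -0.52 (camera p = 7.47e-18, or p = 0.0495 with an estimated correlation). Symbols and not known roles set the choice, and Cfap65, named above among the largest falls, is included. Other genes outside the lists fell too. Anxa1, which encodes annexin A1, fell from 178.1 ± 12.6 to 60.1 ± 15.8 CPM (SD, n = 3 each), the giant cadherin gene Fat2 had a log2 fold change of -1.82 ± 0.10 SE, and the chloride channel gene Cftr one of -0.64 ± 0.07 (edgeR adjusted p of 0.00074 or less for these 3).

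Some collagen genes besides Col11a1 were higher. Col2a1 rose from 209.0 to 418.7 CPM, Col11a2 with a log2 fold change of 0.69 and the collagen crosslinking gene Loxl2 with one of 0.80 ± 0.08 (edgeR adjusted p = 0.00246, 0.00391 and 0.00042), while Col1a1 and Col3a1 had log2 fold changes of 0.08 and 0.00 (edgeR adjusted p = 0.979 and 1.00). The cartilage genes Col9a1 and Col9a3 had log2 fold changes of 0.10 ± 0.12 and 0.16 ± 0.09 (edgeR adjusted p = 0.885 and 0.554). Of the 10 cartilage markers listed for this check, Cnmd alone was called (0.71 ± 0.15, edgeR adjusted p = 0.0255). These 10 did not include Col2a1, Col11a1 or Col11a2, and some were low, such as Matn1 at 0 to 6 counts per library. Rpl30, a ribosomal protein gene on chromosome 15 (34440505 to 34443276), fell by 0.78 ± 0.10 on the log2 scale, and its counts are uncertain because of processed copies. It also lies within 10 Mb of Grhl2. The split of the libraries by genotype called 537 genes and the 9 others called 0 by edgeR, with 113 to 1781 genes at an unadjusted p under 0.05 against 1981; 1 of 10 splits reached that count of calls, and 10 splits are too few for a share under 0.05.

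Grhl2_cKO replicate 1 lay between the groups. On 385 of the 386 genes called from the 4 male libraries, those also tested with all 6, its median position was 0.31 (bootstrap 95% interval over genes, not libraries, 0.276 to 0.337), where 0 is the mean of the male Grhl2_cKO and 1 that of the male control libraries. Of the 337 genes that fell in the fit without it, it was the highest of the 3 Grhl2_cKO libraries in 80.4%. Replicate 5 was the highest in 18.2% of the 165 genes that fell in the fit without replicate 5. Replicate 10 was the highest in 27.1% of the 170 genes that fell without replicate 10. Cells that lack these transcripts would lower the fallen genes, so these values argue against dilution by such cells only. Cells of other types that express the fallen genes would raise them, and this was not tested. For the 134 genes that rose in the fit without Grhl2_cKO replicate 1, it was the lowest in 64.9%. There dilution and a weaker response cannot be told apart. An additive effect of sex would place the female control, replicate 7, above 1, and its position was 0.92 (0.895 to 0.943). The axis genes were chosen from the male libraries, which pulls libraries left out of that choice inward at both ends. A position under 1 therefore does not exclude an additive effect of sex. Part of the 0.31 of Grhl2_cKO replicate 1 can likewise come from this choice. A genotype effect that differs by sex also stays open with 1 female knockout sample. A share of cells that kept control-like Grhl2 activity may exist but cannot be read from these values. For genes that fell 4-fold or more, Grhl2_cKO replicate 1 lay 17.1% (15 to 21.6%, bootstrap over genes) of the way to the male controls on the linear scale. The female control lay 20.3% (7.3 to 34.1%) of the way to the male Grhl2_cKO libraries. For genes that fell under 2-fold these values were 25.5% and 7.7%. Grhl2 in Grhl2_cKO replicate 1 stood at 105.3 CPM, the lowest of the 3 Grhl2_cKO libraries. The share over all fallen genes (22.9%) would bring 120.5 CPM. This difference does not decide the question. It is 1 gene, its reads can come from exons outside the deleted part, and this library held transcripts of other tissues.

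The same library held transcripts of other tissues. The summed heart muscle markers stood at 436.4 CPM in Grhl2_cKO replicate 1 and at 172.0 to 232.2 CPM in the other 5 libraries, with 251 counts of Nppa against 0 to 7, and 76.4 CPM of Myh6 against 9.19 to 14.4. Most of the sum in the other 5 libraries was Myh7, so that sum is not a measure of heart tissue there. Myh7 stood at 138.5 to 146.6 CPM in controls and at 191.6 to 200.6 CPM in Grhl2_cKO. Summed mesenchyme markers were 2530 CPM there, against 1376 to 2273 CPM elsewhere.

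The ciliated and secretory lists were lower while the neuroendocrine list was higher. Fewer airway cells of every kind would lower the 3 lists together, and the neuroendocrine median was 0.40 (bootstrap 95% interval 0.34 to 0.95) against -1.05 (-1.26 to -0.73) for the ciliated list. These intervals resample list members and not libraries, so they do not measure the spread between samples. If neurons gave the higher values, this contrast would not bear on airway cells. Airway neurons in the sort would raise their own markers, such as Hand2 and Prph, and 1 of 3 Grhl2_cKO libraries (replicate 1) exceeded every control in the sum of 8 such markers (5.53 CPM against at most 2.99 CPM). The sums of replicates 5 and 10 (2.50 and 2.49 CPM) lay within the control range, and the 1 marker high enough to be tested, Elavl4, had a log2 fold change of 0.01 ± 0.28 (edgeR adjusted p = 0.998), whereas the neuronal tubulin gene Tubb3 lay above every control in each of the 3 (0.89 to 3.67 CPM against at most 0.37 CPM), as Insm1 did; with the other 7 markers too low to test, neurons and neuroendocrine cells cannot be told apart here. A shift in airway differentiation with the genotype stays a hypothesis, since counts from bulk tissue do not separate cell number from expression per cell.

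A pair of features without a symbol in the gene table, Entrez 100503231 and 100504598, both 177 bases long, were near 0 in controls and present in each Grhl2_cKO library. The first had 1 count over the 3 controls and 86, 71 and 78 counts in Grhl2_cKO replicates 1, 5 and 10, and the second 7 counts over the controls and 55, 55 and 59 counts. Tissue carried into some samples would vary between them, as Nppa did, but the highest Grhl2_cKO library exceeded the lowest by 1.13 times at most. Sequence carried by the null allele or its flanks is a candidate source. Of 60 tested genes within 10 Mb of Grhl2, 5.00% were called (Clopper-Pearson 95% interval 1.04% to 13.9%), against 3.67% elsewhere (Fisher's exact test, two-sided, p = 0.485). This does not separate the possibilities, and the features themselves could not be placed. The genes called there were Dnah5, Snhg18 and Rpl30. For these, an effect of the flanks was not separated from one of Grhl2 loss.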
